A study of Homo sapiens with 7 samples.

How the data were processed

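Nuclei from primary human glioma tumours were assayed with DNA SCIENCE, a method that reads contacts between pieces of DNA around chosen loci. Per the labels' protocols, nuclei were spread over multiwell plates by limiting dilution, crosslinks were reversed with proteinase K, and chosen loci were amplified in a first PCR with locus-specific primers. A second PCR added index barcodes. A read that crosses a ligation junction therefore starts at a chosen locus, called the viewpoint here, and continues into the piece of DNA joined to it, called the partner.

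Per the submitters' processing notes, the work used Bowtie2 and the builds hg38 and GRCh38. The version of Bowtie2, the splitting of reads into segments, the handling of pieces that match several places, and any filtering or merging of equal reads are not given in the sources used here. The values came as a single deposited table of segments attached to the astrocyte sample, which held rows of all 7 cell types. Each deposited row gives the cell type, a running number of the nucleus, the viewpoint, a running number of the read, the order of the segment in the read, and the chromosome, start and end on hg38. The authors' table thus holds positions and no counts, levels or mapping qualities, and every count given here was made by counting its rows. Starts and ends are printed as deposited, and the table does not state whether its starts count from 0 or 1.

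The rows were assigned to samples by the name of the cell type. A name differed from its sample label in 2 cases. Rows named Endothelial were assigned to the sample labelled Encothelial, which differs by 1 letter. Rows named Glioma were assigned to the sample labelled GSC, where the words differ, because GSC was the only label left that names a tumour cell. The names GSC and endothelial cells are used throughout. Viewpoints appeared under 14 spellings, which were read as 12 genes (CDK6 and Cdk6 as CDK6, TERT and hTERT as TERT, cd47, cdc42, HOXBas1 and HOXDas2 as CD47, CDC42, HOXB-AS1 and HOXD-AS2). The number of columns that matched no sample was 0.

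Genes were placed with the RefSeq annotation of GRCh38.p14, which has the positions of 59792 genes. It gives the start and end of each gene without exons, introns or strand, so a position is described only as inside a gene or at a distance from it. The own position of a viewpoint was the first-segment position nearest to the body of its gene. The distance of a partner is the start of the partner minus the start of the own position. A partner was called distal when it lay over 10 kb from the own position or on another chromosome, a definition chosen after the data were examined. All 1442 reads of 5 segments were described apart from the reads of 2 segments. Of the 47901 reads of 2 segments, 2336 had only 1 of their segment rows in the table. A partner was used wherever its row was present, and 995 reads without it, 953 of them spelled hTERT, were not used for partners.

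The comparisons fixed before the data were examined were the number of segments per cell type, the share of segments at the targeted loci, the pairs of targeted loci joined in a read, the share of segment pairs on 1 chromosome, the spread over annotation classes and chromosomes, and the overlap of 10 kb bins between cell types. A segment belonged to a gene when it overlapped the gene body. The bin overlap was set beside 1000 random reassignments of segments to cell types, as a description of these libraries. Alternatives fixed beforehand were counting identical segments of a nucleus once, leaving out segments under 30 bases, keeping the primary chromosomes only, other rules for assigning segments to genes, leaving out near pairs, more reads behind a pair, protein-coding and lncRNA genes only, leaving out the locus with the most segments, other bin sizes, and thinning every cell type to 755 segments with 100 draws. Alternatives for the distal share, over all viewpoints and over the protein-coding viewpoints, and first segments put at the own position of their viewpoint for the share of pairs on 1 chromosome, were chosen after the data were examined. Those for the distal share were limits of 5 and 50 kb, partners of 30 bases or more, reads whose first segment lay at the own position, leaving out the spellings Cdk6 and hTERT, and leaving out the scattered partners of CD44 in oligodendrocytes and of SOX2 in OPC. The labels gave 1 sample per cell type, so no test between cell types was run.

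The rule for named genes was also fixed before the data were examined. It took every viewpoint, every member of the fixed lists with at least 10 segments, the 5 genes with the most segments in each cell type, up to 3 genes per cell type with at least 10 segments whose interval lay above that of all other cell types together, and the 10 gene pairs with the most reads, 1 of which is not reported here. Other genes named at partner sites or first-segment positions were named because the annotation places those sites in or near them, after their values were seen. Fixed lists covered 26 glioma oncogenes and growth genes, 9 tumour suppressors, 26 lncRNAs, telomerase, and 29 cell type markers used as loci only.

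Shares have exact (Clopper-Pearson) 95% intervals and counts have exact Poisson 95% intervals. A share of 0 is given with the limit that 3 counts would make. PCR reads without molecular identifiers are not independent molecules, and intervals and limits cover counting error only. The interval of a bin overlap treats bins as independent trials, which they are not, and does not cover the counting error of segments or the depth. The depth ran from 755 segments in neurons to 63196 in macrophages, so the intervals of neurons are the widest. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1. The computation of distal shares was tested on simulated reads of 3 viewpoints with 2000 reads each. The largest difference from the set share was 1.45 percentage points, which includes the random draw of the simulation. No simulated partner lay near the 10 kb limit, so calls near that limit were not tested.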

Results

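The series profiled DNA contacts between glioma oncogenes and glioma lncRNAs (long non-coding RNA genes) in nuclei of primary glioma tumours. The 7 samples were 7 cell types, with 1 sample each: GSC, OPC, astrocytes, oligodendrocytes, neurons, endothelial cells and macrophages. Rows named Glioma in the table were read as the sample labelled GSC. The table held 100676 segments from 49343 reads in 3563 nuclei. Macrophages gave 63196 segments (95% interval 62704 to 63691) in 1841 nuclei, GSC 19927 (19651 to 20206) in 1074 nuclei and OPC 10265 (10067 to 10466) in 405 nuclei. Astrocytes gave 2526 segments (2428 to 2626) in 88 nuclei, oligodendrocytes 2411 (2316 to 2509) in 84, endothelial cells 1596 (1519 to 1676) in 50 and neurons 755 (702 to 811) in 21. The median number of reads per nucleus was 7 in GSC, 13 in OPC, 15 in astrocytes and in oligodendrocytes, 16 in endothelial cells, 18 in macrophages and 19 in neurons. With 1 sample per cell type no difference between cell types has a replicate check, and differences are given as values with intervals of counting error.

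The 12 viewpoints were promoters of 7 protein-coding genes and 5 lncRNA genes, with positions on hg38. The protein-coding viewpoints were CD44, the hyaluronan receptor of the cell surface, at chromosome 11, 35139635 to 35139651, inside the gene, and CD47, the surface signal that restrains phagocytosis, at chromosome 3, 108091906 to 108091922, 876 bp outside it. CDC42, a small GTPase of the cytoskeleton, was read at chromosome 1, 22053780 to 22053796, and CDK6, a kinase of the G1 phase, at chromosome 7, 92833304 to 92833320, each inside its gene. EGFR, a growth factor receptor often amplified in glioblastoma, was read at chromosome 7, 55018790 to 55018806, 211 bp outside the gene. SOX2, a transcription factor of neural progenitors, was read at chromosome 3, 181711904 to 181711920, 5 bp outside SOX2 and inside SOX2-OT. TERT, the catalytic subunit of telomerase, was read at chromosome 5, 1295426 to 1295442, 359 bp outside the gene. The lncRNA viewpoints belonged to the HOX clusters or their surroundings. They were HOTAIR at chromosome 12, 53973566 to 53973582, HOTAIRM1 at chromosome 7, 27096762 to 27096778, and HOXB-AS1 at chromosome 17, 48545240 to 48545256, each inside its gene. HOXD-AS2 was read at chromosome 2, 176138077 to 176138093, 980 bp outside the gene and inside LOC401021, and LINC01116 on the same chromosome at 176637750 to 176637766, 142 bp outside the gene and inside LINC01117.

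In GSC, single reads from HOTAIRM1 and LINC01116 held pieces in or within 10 kb of 5 lncRNA loci on 4 chromosomes. This takes the first segment at the own position of its viewpoint. The reads are PCR products, and whether their pieces were joined in the nucleus was not tested. All 533 HOTAIRM1 reads (99.3 to 100%) and all 909 LINC01116 reads (99.6 to 100%) of GSC had 5 segments. How reads were selected, filtered or merged before they were deposited is not given in the sources used here, so shares of 100% describe the deposited reads. Reads of 5 segments occurred in 1024 of 1074 GSC nuclei, 95.3% (93.9 to 96.5), and 235 nuclei, 21.9% (19.4 to 24.5), had a read of each viewpoint. No read with 5 segments was seen in the other cell types. For HOTAIRM1 the counts were 0 of 2510 reads in macrophages (up to 0.12%), 0 of 581 in OPC (up to 0.516%), 0 of 128 in astrocytes (up to 2.34%), 0 of 112 in oligodendrocytes (up to 2.68%), 0 of 68 in endothelial cells (up to 4.41%) and 0 of 39 in neurons (up to 7.69%). For LINC01116 they were 0 of 2554 in macrophages (up to 0.117%), 0 of 562 in OPC (up to 0.534%), 0 of 135 in astrocytes (up to 2.22%), 0 of 113 in oligodendrocytes (up to 2.65%), 0 of 65 in endothelial cells (up to 4.62%) and 0 of 41 in neurons (up to 7.32%).

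Each of these reads passed through the same 3 middle pieces. They lay at chromosome 12, 53975809 to 53975830, in HOXC11 beside HOTAIR, at chromosome 17, 48545260 to 48545287, in HOXB-AS1, and at chromosome 2, 176138051 to 176138093, in LOC401021 beside HOXD-AS2. Reads from HOTAIRM1 ended at chromosome 2, 176636890 to 176636918, inside LINC01116. Reads from LINC01116 ended on chromosome 7 within 10 kb of HOTAIRM1. HOTAIR, HOXB-AS1 and HOXD-AS2 were thus reached as partners in GSC, while each had 0 reads as a viewpoint there, in 0 of 1074 nuclei (up to 0.279%). The piece in LOC401021 contains the HOXD-AS2 viewpoint, 176138077 to 176138093. The piece in HOXB-AS1 starts directly beside the HOXB-AS1 viewpoint, 48545240 to 48545256. Whether these viewpoint positions, amplified in the same assay, bear on the joins or on the 0 viewpoint reads was not tested. The order of the middle pieces varied. HOTAIRM1 reads showed 3 of the 6 possible orders, led by HOXD-AS2, HOTAIR, HOXB-AS1 in 206 of 533 reads, 38.6% (34.5 to 42.9). LINC01116 reads showed 5 of the 6, each in 19.1 to 21.3% of 909 reads, and the missing order, HOTAIR, HOXB-AS1, HOXD-AS2, made up 163 HOTAIRM1 reads, 30.6% (26.7 to 34.7).

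**Figure D1:**
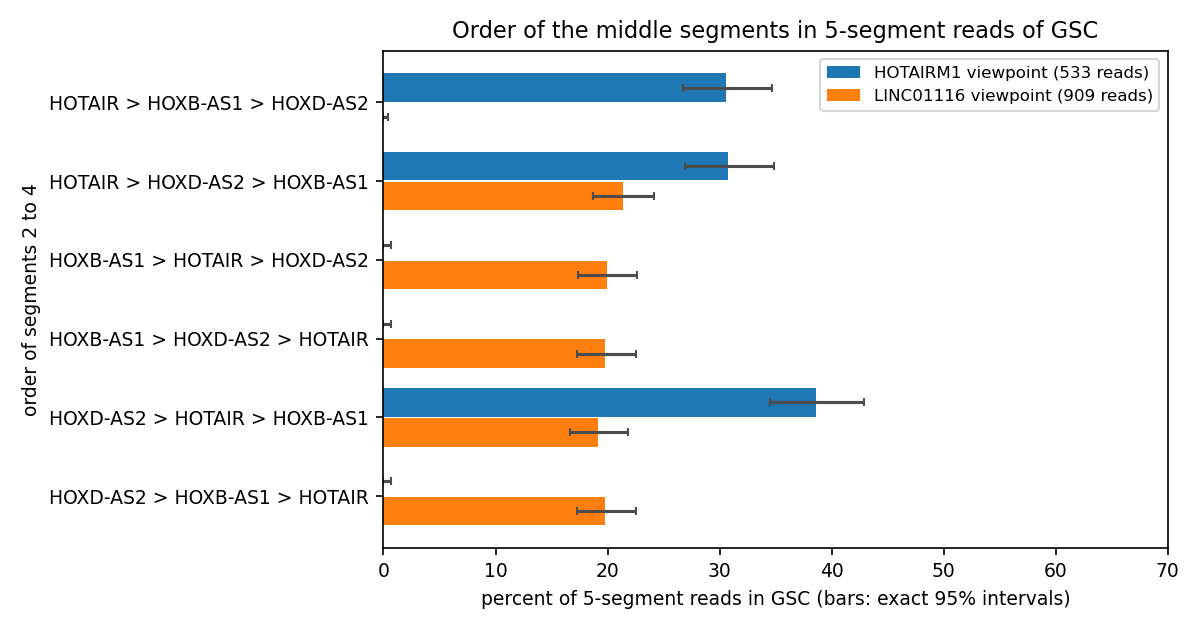
Percent of the reads of 5 segments in GSC (horizontal axis) that showed each order of segments 2 to 4 (vertical axis), for the HOTAIRM1 viewpoint (533 reads, blue) and the LINC01116 viewpoint (909 reads, orange). Lines are exact 95% intervals of counting error, and the orders without a bar had 0 reads.

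The pairs of targeted loci joined in a read were counted by gene body, the rule fixed beforehand, and with 10 kb added on each side. By gene body, GSC joined 3 pairs, HOTAIRM1 with HOXB-AS1, HOTAIRM1 with LINC01116 and HOXB-AS1 with LINC01116, each in 533 reads (489 to 580). With 10 kb on each side, GSC joined all 10 pairs of the 5 lncRNA loci. The pairs among HOTAIR, HOTAIRM1, HOXB-AS1 and HOXD-AS2 had 1442 reads each (1369 to 1518), and the 4 pairs with LINC01116 had 1017 (955 to 1081). The lower number leaves out 425 LINC01116 reads whose first segment the table places on chromosome 17. By either rule the other cell types joined 0 pairs, and in no cell type was a protein-coding viewpoint gene joined to a targeted lncRNA. The limit was 3 reads of 30848 in macrophages, 0.00973%, and rose to 0.815% of 368 reads in neurons.

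The series asks which glioma oncogenes meet lncRNA genes, and distal partners of the oncogene viewpoints were most frequent in GSC. Over the 7 protein-coding viewpoints, 86.5% of 6299 partners were distal in GSC (85.6 to 87.3), 60.8% of 2226 in OPC (58.8 to 62.9), 30.1% of 657 in astrocytes (26.6 to 33.8) and 24.7% of 619 in oligodendrocytes (21.4 to 28.3). The share was 18.3% of 443 in endothelial cells (14.8 to 22.2), 5.15% of 18992 in macrophages (4.84 to 5.48) and 4.63% of 216 in neurons (2.24 to 8.35). More than 20% of the reads had distal partners for 7 of 7 protein-coding viewpoints in GSC, 5 in OPC, 3 in astrocytes, 3 in oligodendrocytes, 2 in endothelial cells, 1 in neurons and 1 in macrophages. Without the spellings Cdk6 and hTERT, 5 viewpoints remained in GSC, 4 in OPC, 2 in astrocytes, 2 in oligodendrocytes and 1 in endothelial cells. A limit of 50 kb gave 5 in GSC and 4 in OPC, and partners of 30 bases or more gave 6 and 4. A limit of 5 kb gave 4 in astrocytes and in oligodendrocytes, 3 in endothelial cells, and 2 in neurons and in macrophages. In oligodendrocytes 60 of the distal partners were CD44 partners scattered over 17 chromosomes, and without them 16.6% of 559 partners (13.6 to 19.99) and 2 viewpoints remained, a share below that of endothelial cells. Without the spellings Cdk6 and hTERT the share was 1.5% in macrophages (1.33 to 1.69) and 0 of 206 in neurons (up to 1.46%), with 0 viewpoints above 20% in each, and with a limit of 5 kb it was 9.68% (9.27 to 10.1) and 12.96% (8.79 to 18.2). With a limit of 50 kb the share of endothelial cells was 8.8% (6.34 to 11.8), and with first segments at the own position only it was 46.3% in astrocytes, 38.2% in oligodendrocytes, 30.8% in endothelial cells and 1.12% in neurons. By construction the own-position setting keeps 100% of CD44 first segments and 10.04% of those of EGFR. It thus gives CD44 more weight in the pooled share. On their own chromosomes the 7 viewpoints had 18 distal sites with at least 10 reads in a cell type, of which 10 lay inside a lncRNA gene, 1 of these also inside the protein-coding gene CD44, and 7 lay outside annotated genes. The TERT sites at 1363711 to 1363779 and 1363780 to 1363868, both inside LINC01511, are adjacent pieces counted apart. No background share of lncRNA genes around these loci was computed, so the count does not show a preference for them. The lncRNA viewpoints outside GSC stayed local, with 0.474% of 12868 partners distal in macrophages (0.363 to 0.609) and 0.556% of 2880 in OPC (0.318 to 0.901). Their partners lay within 8.28 kb of the viewpoint for HOTAIR, 3.46 kb for HOTAIRM1, 6.22 kb for HOXB-AS1, 3.9 kb for HOXD-AS2 and 5.37 kb for LINC01116, apart from the distal partners of HOXB-AS1. Over all 12 viewpoints, a set GSC lacks because it had no reads of 2 segments from lncRNA viewpoints, the distal share was 26.8% of 5106 partners in OPC (25.6 to 28.1), 15.97% of 1265 in astrocytes (13.99 to 18.1), 13.2% of 1201 in oligodendrocytes (11.3 to 15.2), 10.3% of 794 in endothelial cells (8.3 to 12.7), 3.26% of 31860 in macrophages (3.07 to 3.47) and 2.62% of 381 in neurons (1.27 to 4.77). These shares moved with the same settings, to 8.59% in oligodendrocytes without the scattered CD44 partners (7.03 to 10.4), and to 1.08% in macrophages and 0% in neurons without the spellings Cdk6 and hTERT. With a limit of 5 kb they were 23.3% in oligodendrocytes, 21.0% in endothelial cells, 10.97% in macrophages and 9.71% in neurons.

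**Figure D2:**
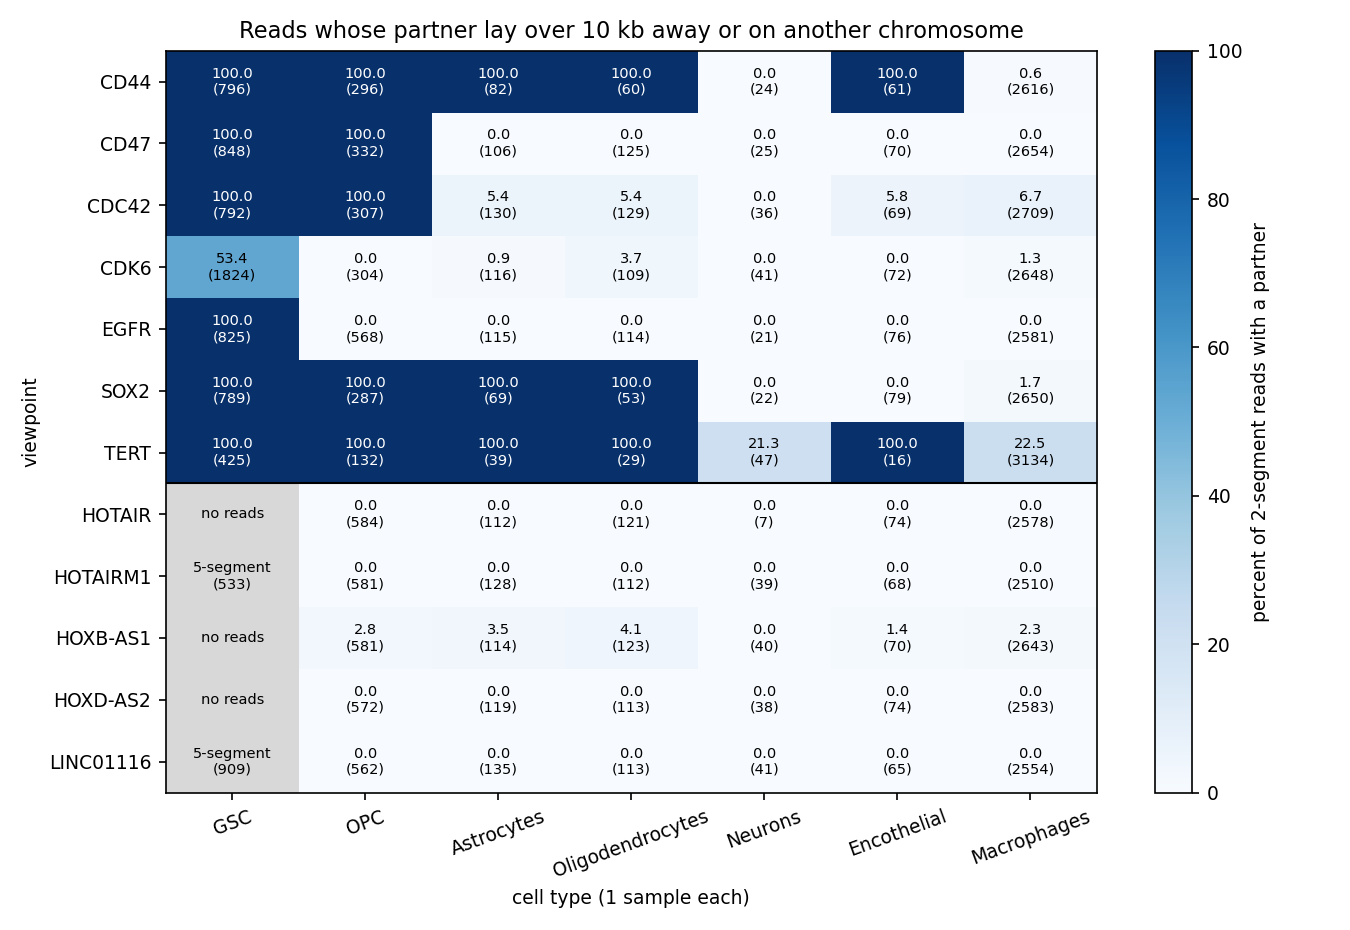
Percent of the reads of 2 segments with a distal partner, over 10 kb away or on another chromosome (shade and upper number), with the number of reads in parentheses, for 12 viewpoints (rows) in 7 cell types (columns, 1 sample each). GSC and OPC both stood at 100% for CD44, CD47, CDC42, SOX2 and TERT, EGFR reached 100% in GSC and 0 in OPC, and the lncRNA viewpoints were below 5% wherever they had partners.

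CD44 had different distal sites in GSC, OPC, astrocytes and endothelial cells, and SOX2 had 3 leading distal sites, of which astrocytes and oligodendrocytes shared 1. CD44 in GSC was joined to a single place 130.4 kb away, chromosome 11, 35009283 to 35009333, inside LOC105376626, in 796 of 796 reads (99.5 to 100%). In OPC it was joined to a place 56.4 kb away at 35083224 to 35083300, inside LOC105376627, in 296 of 296 reads (98.8 to 100%). Astrocytes had 2 CD44 sites, 30.2 kb away at 35109464 to 35109574 and 98.7 kb away at 35238335 to 35238465, in 41 of 82 reads each, 50% (38.7 to 61.3). Endothelial cells had 3, at 35111592 to 35111627 in 27 of 61 reads, at 35214820 to 35214896 inside CD44 and CD44-AS1 in 19, and at 35099694 to 35099772 in 15. CD44 stayed within 2.72 kb in macrophages apart from 16 of 2616 reads, 0.612% (0.35 to 0.991), and 0 of 24 reads were distal in neurons (up to 12.5%). In oligodendrocytes the 60 CD44 partners fell on 55 positions over 17 chromosomes.

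SOX2 in GSC was joined to a place 240.4 kb away, chromosome 3, 181952325 to 181952353, outside annotated genes, in 789 of 789 reads (99.5 to 100%). The partners at this GSC site had 19 to 28 bases. In astrocytes and oligodendrocytes it was joined to a place 269 kb away on the opposite side, at 181442409 to 181442466 inside SOX2-OT and LOC102724604, in 69 of 69 reads (94.8 to 100%) and 53 of 53 (93.3 to 100%). In OPC the leading SOX2 site was 1031 kb away at 180680682 to 180680703, inside CCDC39-AS1 and beyond the genes FXR1 and DNAJC19, in 219 of 287 reads, 76.3% (71.0 to 81.1). The other 68 OPC reads lay over 19 chromosomes. Distal SOX2 partners were 0 of 79 in endothelial cells (up to 3.8%), 0 of 22 in neurons (up to 13.6%) and 44 of 2650 in macrophages, 1.66% (1.21 to 2.22).

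CD47 and CDC42 shared their distal site between GSC and OPC. CD47 was joined to chromosome 3, 107240824 to 107240954, inside the lncRNA gene DUBR and 851 kb away, past the genes BBX and CCDC54, in 848 of 848 GSC reads (99.6 to 100%) and 332 of 332 OPC reads (98.9 to 100%). No CD47 partner was distal in the other cell types, with 0 of 2654 reads in macrophages (up to 0.113%), 0 of 125 in oligodendrocytes (up to 2.4%), 0 of 106 in astrocytes (up to 2.83%), 0 of 70 in endothelial cells (up to 4.29%) and 0 of 25 in neurons (up to 12%). CDC42 was joined to chromosome 1, 22025418 to 22025503, 28.4 kb away inside LINC00339 and LINC01635, in 792 of 792 GSC reads (99.5 to 100%) and 307 of 307 OPC reads (98.8 to 100%). Elsewhere CDC42 was mostly local, with distal shares of 6.68% in macrophages (5.77 to 7.69), 5.8% in endothelial cells (1.6 to 14.2), 5.43% in oligodendrocytes (2.21 to 10.9) and 5.38% in astrocytes (2.19 to 10.8), and 0 of 36 in neurons (up to 8.33%).

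EGFR and CDK6 were joined to far sites in GSC. EGFR was joined to chromosome 7, 55254694 to 55254824, inside the lncRNA gene ELDR, 43.1 kb beyond the body of EGFR and 235.9 kb from the viewpoint, in 825 of 825 GSC reads (99.6 to 100%). Its distal share was 0 of 2581 in macrophages (up to 0.116%), 0 of 568 in OPC (up to 0.528%), 0 of 115 in astrocytes (up to 2.61%), 0 of 114 in oligodendrocytes (up to 2.63%), 0 of 76 in endothelial cells (up to 3.95%) and 0 of 21 in neurons (up to 14.3%). CDK6 in GSC had 2 sites. The farther, 137.7 kb away at chromosome 7, 92971021 to 92971079 inside the pseudogene RN7SL7P, took 974 of 1824 reads, 53.4% (51.1 to 55.7), and these were the reads spelled Cdk6. That spelling occurred in GSC only, so the other cell types had no such reads to compare. The remaining 850 GSC reads and all 304 OPC reads lay at a place 2.76 kb away. Without the reads spelled Cdk6, the distal share of CDK6 in GSC was 0%. Elsewhere it was 3.67% of 109 reads in oligodendrocytes (1.01 to 9.13), 1.28% of 2648 in macrophages (0.891 to 1.79) and 1 of 116 in astrocytes, and 0 in OPC, neurons and endothelial cells (limits of 0.987, 7.32 and 4.17%).

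TERT had a distal site in each of the 7 cell types, in the reads spelled hTERT. In GSC the site was 49.9 kb away at chromosome 5, 1345348 to 1345448, 250 bp from CLPTM1L, in 425 of 425 reads with a partner (99.1 to 100%), while 291 of the 716 GSC reads spelled hTERT, 40.6%, had no partner row. In OPC it was 53.4 kb away at 1348798 to 1348928 in 132 of 132 (97.2 to 100%). The other cell types used neighbouring places inside LINC01511. Astrocytes (39 of 39 reads), endothelial cells (16 of 16) and macrophages (704 of 3134, 22.5%, 21.0 to 24.0) had 1363711 to 1363779, 68.3 kb away. Oligodendrocytes (29 of 29) and neurons (10 of 47, 21.3%, 10.7 to 35.7) had 1363780 to 1363868, 68.4 kb away. Of the 995 reads without a partner row in the table, 953 were spelled hTERT, at 32.8 to 55.6% of these reads in each cell type. The spelling TERT occurred in macrophages and neurons only, with local partners, and 0% of the TERT partners were distal there once hTERT was left out. The shares of 22.5 and 21.3% count both spellings. Of the partners spelled hTERT alone, 100% of 704 in macrophages and 100% of 10 in neurons were distal.

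**Figure D3:**
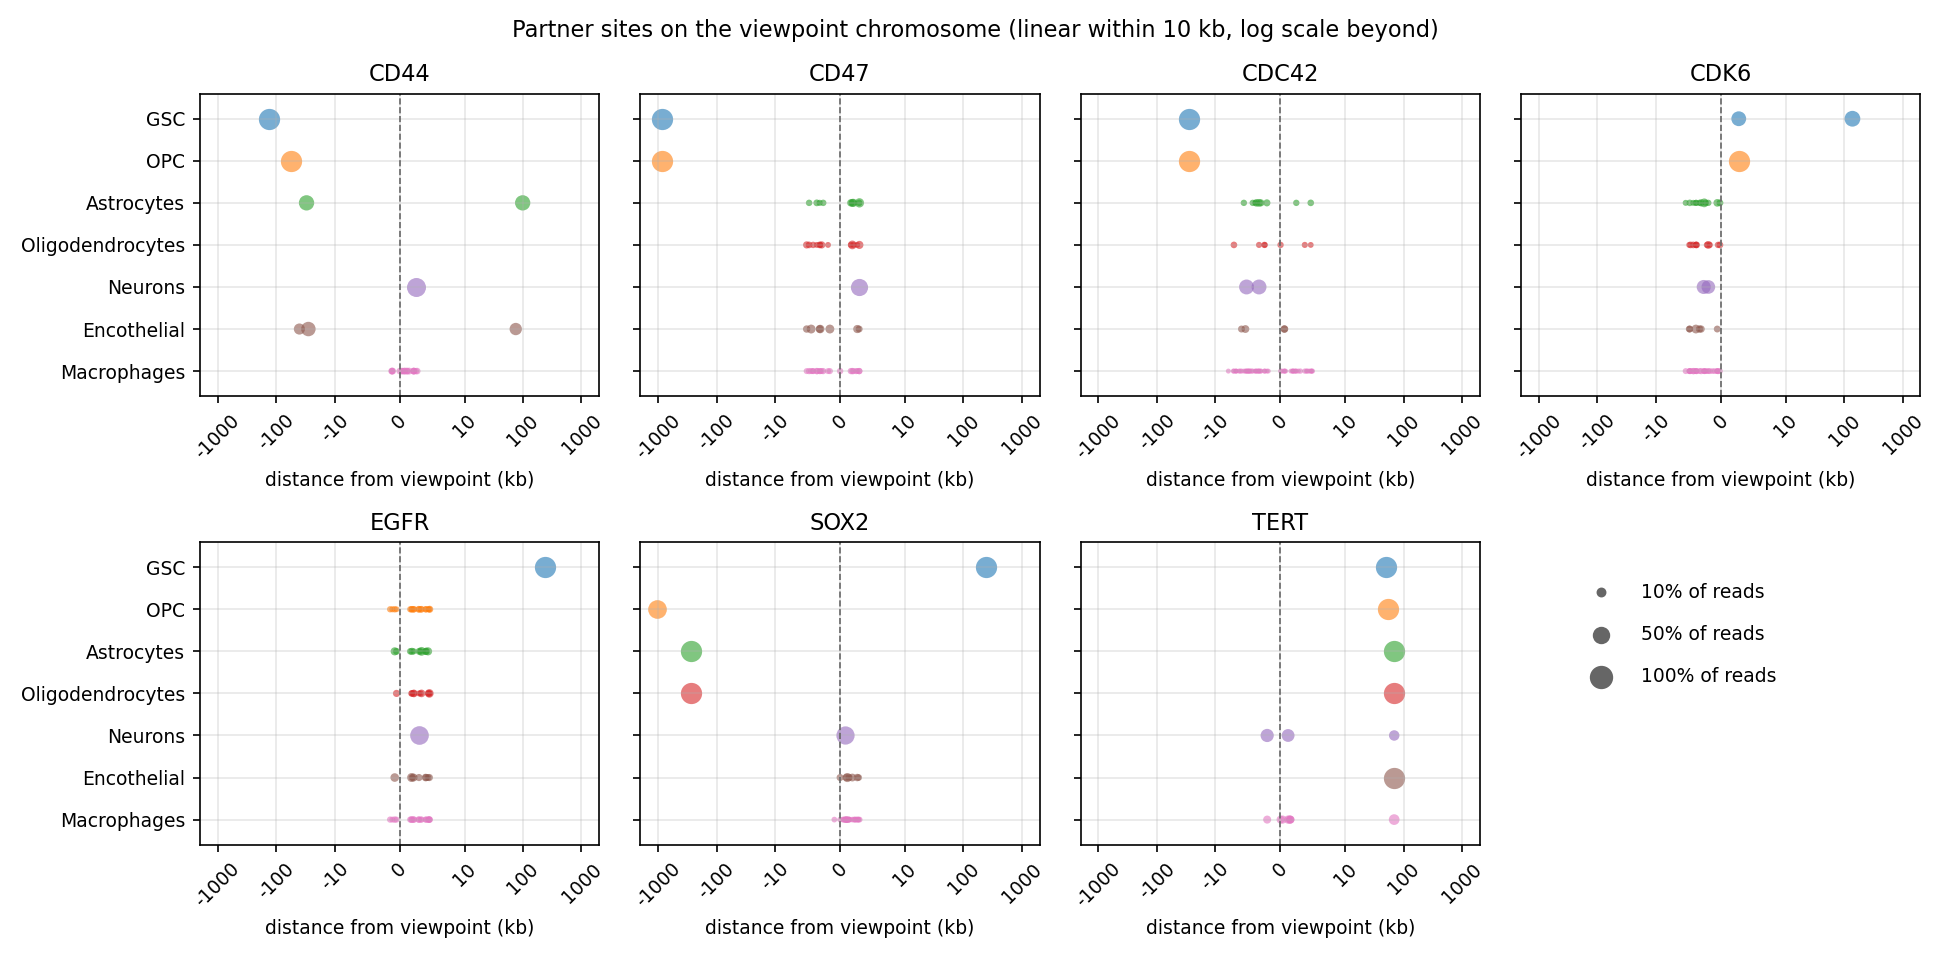
Distance of partner sites from the viewpoint in kb (horizontal axis, linear within 10 kb and logarithmic beyond) for 7 protein-coding viewpoints in 7 cell types (rows), each circle being a site with at least 5 reads and its area growing with the percent of reads. GSC and OPC had the same site for CD47 (851 kb) and CDC42 (28.4 kb), and different sites for CD44 (130.4 and 56.4 kb) and SOX2 (240.4 and 1031 kb). These SOX2 sites rest on partners of 19 to 28 bases in GSC and 12 to 21 bases in OPC.

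Among all annotated genes, HOXB-AS1 held the most segments, 8109 of 100676 or 8.05%, followed by LOC401021 with 7311, CDK6 with 6957, HOTAIR with 6952 and HOTAIRM1 with 6629. In GSC the leading genes were CDK6 with 9.82% of segments (9.41 to 10.2), HOXB-AS1, HOXC11 and LOC401021 with 7.24% each (6.88 to 7.6) and RN7SL7P with 4.89% (4.59 to 5.2). In OPC they were HOTAIR with 11.4% (10.8 to 12.0), HOXB-AS1 with 10.3%, HOTAIRM1 with 10.1%, LOC401021 with 9.38% and HOXC11 with 5.69%. HOTAIR, HOTAIRM1, HOXB-AS1 and LOC401021 were also among the 5 leading genes of astrocytes, oligodendrocytes, endothelial cells and macrophages, joined by CDK6 in astrocytes (6.69%) and oligodendrocytes (6.18%), by SOX2-OT in endothelial cells (8.02%, 6.73 to 9.46) and by CD44 in macrophages (7.45%, 7.25 to 7.66). In neurons HOXB-AS1 led with 10.6% (8.49 to 13.01), followed by LOC401021, HOTAIRM1, CDK6 and LOC124905596 at the TERT viewpoint, and HOTAIR reads were found in 5 of 21 neurons against 1793 of 1841 macrophages.

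Several genes that hold a distal partner site had segments in a single cell type. RN7SL7P, ELDR and LOC105376626 had 974, 825 and 796 segments in GSC and 0 of 80749 in the other cell types together (up to 0.00372%). The RN7SL7P segments all came from reads spelled Cdk6, a spelling found in GSC only, so its 0 elsewhere compares unlike reads. LOC105376627, CCDC39-AS1 and EP300-AS1 had 296, 219 and 14 in OPC and 0 of 90411 elsewhere (up to 0.00332%), where the 14 of EP300-AS1 were SOX2 partners of 14 to 15 bases, among the OPC partners scattered over 19 chromosomes. The 219 of CCDC39-AS1 were SOX2 partners of 12 to 21 bases. CD44-AS1 had 19 in endothelial cells and 0 of 99080 elsewhere (up to 0.00303%), and LINC01847 had 16 in macrophages and 0 of 37480 elsewhere (up to 0.008%). The 16 of LINC01847 were CD44 partners of 17 to 19 bases. LOC102724604, which overlaps SOX2-OT, held 2.73% of astrocyte segments (2.13 to 3.44) and 2.2% of oligodendrocyte segments (1.65 to 2.87). Other genes passed the interval rule against all other cell types together, where GSC, with 0 segments in SOX2, TERT, CD47, HOXB3, HOXD-AS2 and LINC01511, lowers the pooled share. SOX2 held 3.34% of segments in macrophages (3.2 to 3.48), 3.88% in endothelial cells (2.99 to 4.95) and 2.91% in neurons (1.83 to 4.38), and none in the other cell types. TERT held 2.25% in neurons (1.32 to 3.58), 0.544% in macrophages (0.488 to 0.605) and none elsewhere. CORO7, where TERT first segments were also placed, held 2.52% in neurons (1.52 to 3.9), 1.48% in macrophages (1.39 to 1.58), 1.06% in GSC (0.921 to 1.21) and 0.664 to 0.877% in the other cell types. HOXB3 held 3.05% in neurons (1.94 to 4.54), 1.98% in astrocytes (1.47 to 2.6), 1.95% in oligodendrocytes (1.44 to 2.58), 2.05% in OPC (1.78 to 2.34), 1.69% in endothelial cells (1.12 to 2.45) and 1.34% in macrophages (1.25 to 1.43). CD47 held 3.2% in endothelial cells (2.39 to 4.18), 2.86% in oligodendrocytes (2.23 to 3.61), 2.53% in macrophages (2.41 to 2.66), 1.66% in astrocytes (1.2 to 2.24), 0.662% in neurons (0.215 to 1.54) and none in OPC. HOXD-AS2 held 3.38% in endothelial cells (2.55 to 4.39), 2.57% in OPC (2.27 to 2.9), 2.16% in oligodendrocytes (1.61 to 2.82), 2.05% in macrophages (1.94 to 2.16), 1.74% in astrocytes (1.27 to 2.33) and 0.662% in neurons (0.215 to 1.54). LINC01511, at the distal TERT site, held 1.54% in astrocytes (1.1 to 2.1), 1.32% in neurons (0.637 to 2.42), 1.2% in oligodendrocytes (0.807 to 1.72), 1.11% in macrophages (1.03 to 1.2), 1.0% in endothelial cells (0.574 to 1.62) and none in OPC.

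The gene pairs with the most reads followed the local contacts and the GSC reads of 5 segments. HOTAIR with HOXC11, whose gene bodies both cover the HOTAIR viewpoint, had 3476 reads (3361 to 3594), 2578 of them in macrophages and 0 in GSC. HOXD-AS2 with LOC401021 had 1713 and HOXB-AS1 with HOXB3 had 1205, and these too had 0 in GSC. HOXB-AS1 with HOXC11, HOXB-AS1 with LOC401021, and HOXC11 with LOC401021 had 1442 reads each, all in GSC. SOX2 with SOX2-OT had 1090 reads, none of them in GSC, OPC, astrocytes or oligodendrocytes. The pairs of KDM2B with SOX2-OT (1428 reads) and with SOX2 (1105) came from SOX2 first segments that the table places in KDM2B on chromosome 12.

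The share of segments at the targeted loci was lowest in GSC. GSC had the highest distal share over the protein-coding viewpoints and no reads from the HOTAIR, HOXB-AS1 and HOXD-AS2 viewpoints. Whether either lowered the share at the targeted loci was not tested. By gene body it was 28.6% in GSC (28.0 to 29.2), 51.9% in OPC (50.9 to 52.8), 50.8% in astrocytes (48.8 to 52.8), 54.0% in oligodendrocytes (52.0 to 56.0), 48.6% in neurons (44.99 to 52.2), 57.6% in endothelial cells (55.1 to 60.02) and 54.8% in macrophages (54.4 to 55.2). With 10 kb on each side, which takes in the viewpoints just outside their genes, it was 54.5% in GSC (53.8 to 55.2) and 71.8 to 80.4% in the other cell types. Of the fixed lists, 3 of 26 oncogenes and growth genes (EGFR, CDK6 and SOX2), 3 of 26 lncRNAs (HOTAIR, HOTAIRM1 and SOX2-OT) and TERT had at least 10 segments, all of them viewpoints or neighbours of one. None of the 9 tumour suppressors had a segment. Of the 29 cell type markers, SOX2 had at least 10 segments and the neuronal gene RBFOX3 had fewer.

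Partners lay mostly on the chromosome of their viewpoint. As the table places the segments, 24.4% of segment pairs in GSC (23.8 to 25.0) lay on the same chromosome, against 75.1% in OPC (73.9 to 76.3), 71.5% in endothelial cells (68.2 to 74.6), 70.8% in astrocytes (68.2 to 73.3), 67.7% in macrophages (67.2 to 68.2), 66.6% in neurons (61.5 to 71.4) and 66.2% in oligodendrocytes (63.4 to 68.9). These values depend on where the table puts the first segments of 7 viewpoints, CD47, CDC42, CDK6, EGFR, LINC01116, SOX2 and TERT, which appear at 25 positions in all. With each first segment at the own position of its viewpoint, reads of 2 segments were on 1 chromosome in 100% of 6127 pairs in GSC, 100% of 368 in neurons, 99.4% in endothelial cells, 99.0% in astrocytes and in macrophages, 98.4% in OPC and 93.8% in oligodendrocytes. With the reads of 5 segments included, the GSC share was 36.8% (36.2 to 37.5).

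Chromosome 7, with the viewpoints CDK6, EGFR and HOTAIRM1, held the most segments in each cell type. Its share was 28.6% in GSC (27.9 to 29.2), 24.7% in OPC (23.9 to 25.6), 24.1% in astrocytes (22.5 to 25.8), 23.97% in oligodendrocytes (22.3 to 25.7), 22.8% in neurons (19.8 to 25.9), 22.7% in endothelial cells (20.7 to 24.9) and 20.9% in macrophages (20.6 to 21.2). Annotated genes held 84.9% of segments in GSC (84.4 to 85.4), 90.5% in OPC (89.9 to 91.0), 87.3% in macrophages (87.1 to 87.6), 85.6% in endothelial cells (83.8 to 87.3), 84.4% in oligodendrocytes (82.9 to 85.9), 84.2% in neurons (81.4 to 86.8) and 81.9% in astrocytes (80.4 to 83.4). The share inside lncRNA genes was 66.0% in OPC (65.0 to 66.9) and 42.2% in GSC (41.5 to 42.9). The share inside protein-coding genes was 49.2% in macrophages (48.8 to 49.6) and 31.7% in OPC (30.8 to 32.6).

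At full depth neurons and endothelial cells shared most of their 10 kb bins, and the number of bins was highest in macrophages, the deepest sample. Macrophages had segments in 208 bins, oligodendrocytes in 108, OPC in 95, astrocytes in 53, endothelial cells in 44, neurons in 39 and GSC in 37. The overlap was 38 of 45 bins between neurons and endothelial cells, 84.4% (70.5 to 93.5), where random reassignment of segments to cell types gave a median of 76.9% (61.1 to 89.1 over 1000 draws). Intervals of overlaps treat bins as independent trials and do not cover the depth. GSC shared 30 of 46 bins with neurons, 65.2% (49.8 to 78.6; reassigned median 37.4%), 33 of 99 with OPC, 33.3% (24.2 to 43.5; reassigned median 40.8%), and 30 of 215 with macrophages, 13.95% (9.62 to 19.3; reassigned median 27.4%). Thinned to 755 segments per cell type, the overlap was highest between neurons and macrophages, 89.5% against 18.75% at full depth, followed by 86.1% between neurons and endothelial cells. It was 78.6% between endothelial cells and macrophages, and that of GSC was 66.8% with OPC and 58.2% with macrophages.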

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

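All tests in this part were chosen after the results they measure were seen. The table places 37.1% of first segments (36.6 to 37.5), the piece at the viewpoint itself, outside the position of their viewpoint, a signal that the partner comparisons leave aside. It concerned 7 of 12 viewpoints, which appeared at 25 positions, such as EGFR at ARID1B, INTS3 and the 3 related genes RASA4, RASA4B and RASA4CP, SOX2 at KDM2B, CDC42 at CSMD1 and TERT at ANKRD50 and CORO7. In each of the 49 combinations of these viewpoints with a cell type, every position of the viewpoint occurred. The own position held 10.04% of EGFR first segments (equal share 10%), 33.5% for TERT (33.3%), 26.2% for CD47 (25%), 49.0% for SOX2 (50%), 51.3% for CDC42 (50%), 46.5% for LINC01116 (50%) and 55.8% for CDK6 (50%), and 12 of 49 combinations had a 95% interval without the equal share, where chance gives 2.45. First-segment rows were present for 3914 of 4300 EGFR reads and 3820 of 4775 TERT reads. The shares of EGFR and TERT leave out the reads without this row.

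If reads had started from DNA at the other places through mispriming, with partners as local as elsewhere, partners should often lie there. When the first segment lay at the own position, 85.8% of partners (85.4 to 86.2) lay within 10 kb of it, over all 12 viewpoints. Instead 0 of 16725 partners lay within 10 kb of the other place (up to 0.0179%), and 77.2% lay within 10 kb of the own position, which argues against such a start. The 77.2% covers only the 7 viewpoints with several positions, so its difference from 85.8% compares unlike sets of viewpoints. A contact between chromosomes that joins the other place to the own locus would also put partners near the own position. The test therefore cannot decide on such a contact. That each matching position was picked with equal chance, read by read, is argued against for CDC42, CDK6 and LINC01116, where 4 of 21 combinations with a cell type differ from equal shares in exact two-sided binomial tests with Bonferroni correction over all 49, and stays open for CD47, EGFR, SOX2 and TERT, where 0 of 28 do. What also stays open is that pieces of 16 bases match several places and that the aligner may have put them at any of these by a rule not known here, a hypothesis that goes with the 0% of partners near the other place and that was not checked against a genome sequence.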

How the results depend on the processing

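Values with no replicate spread were compared with their exact 95% interval. Of the values per cell type, or per pair of cell types for the overlap, 122 left that interval under an alternative and 109 stayed within it. For the overlap the interval does not cover the counting error of segments, so these counts are a description. At the level of single viewpoints 46 left it and 420 stayed. The alternatives for first-segment places, for the distal share and for reads of 5 segments were chosen after seeing the data, and the others before. The cause was not tested unless stated. Values follow the order GSC, OPC, astrocytes, oligodendrocytes, neurons, endothelial cells, macrophages unless cell types are named.

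By construction fewer segments remained when identical segments of a nucleus were counted once (17708, 9375, 2258, 2157, 638, 1410 and 55961) and when segments under 30 bases were left out (6952, 4719, 1245, 1156, 367, 753 and 30388), since first segments have 16 bases. The share at targeted loci was 12.2, 59.6, 57.3, 63.8, 59.4, 73.7 and 67.6% without segments under 30 bases. With 10 kb on both sides of the gene body, a wider target by construction, it was 54.5, 71.8, 76.6, 76.2, 80.4, 79.1 and 80.3%, and GSC joined 10 locus pairs in place of 3. Counting identical segments once gave 26.9% in GSC and 50.8% in OPC, and the midpoint rule gave 50.6% in OPC and 53.9% in macrophages.

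The share of segment pairs on 1 chromosome was 36.8, 98.4, 99.0, 93.8, 100, 99.4 and 99.0% with first segments at the own position of the viewpoint. It was 22.5, 43.6, 34.1, 20.4, 9.56, 30.7 and 13.1% without pairs under 20 kb apart, which by construction removes same-chromosome pairs alone, as does the limit of 1 kb (71.7% in OPC, 66.9% in astrocytes, 61.3% in oligodendrocytes, 61.1% in neurons, 67.6% in endothelial cells and 61.9% in macrophages). Counting pairs of identical coordinates once gave 35.8% in GSC, 65.3% in OPC, 66.5% in astrocytes, 62.6% in oligodendrocytes, 67.5% in endothelial cells and 51.9% in macrophages.

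The share inside annotated genes was 79.6% in GSC, 89.9% in OPC and 87.0% in macrophages for protein-coding and lncRNA genes only. Without HOXB-AS1, the locus with the most segments, it was 83.7% in GSC, 89.4% in OPC, 80.3% in astrocytes, 82.9% in oligodendrocytes and 86.2% in macrophages. Bin overlap rose to 35.7% between GSC and macrophages and 66% between GSC and OPC with at least 2 segments in a bin, and to 58.2 and 66.8% when thinned to the smallest cell type. With bins of 1 kb it was 62.1% between neurons and endothelial cells.

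Over all viewpoints the distal share with a limit of 5 kb was 33.8% in OPC, 22.1% in astrocytes, 23.3% in oligodendrocytes, 9.71% in neurons, 21.0% in endothelial cells and 11.0% in macrophages. With a limit of 50 kb it was 67.2% in GSC, 20.8% in OPC, 12.7% in astrocytes and 5.04% in endothelial cells. With first segments at the own position only it was 83.7% in GSC, 21.7% in OPC, 0.429% in neurons and 2.02% in macrophages. By construction this keeps all first segments of viewpoints with a single position and a part of the others, which changes the weights of the viewpoints. Partners of 30 bases or more gave 84.6% in GSC, 22.6% in OPC and 2.81% in macrophages. Without the spellings Cdk6 and hTERT it was 82.7% in GSC, 24.9% in OPC, 13.3% in astrocytes, 11.0% in oligodendrocytes, 0% in neurons and 1.08% in macrophages. Without the scattered partners of CD44 and SOX2 it was 8.59% in oligodendrocytes, which by construction takes out 60 distal partners.

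Over the protein-coding viewpoints alone, the distal share with first segments at the own position only was 83.7, 74.6, 46.3, 38.2, 1.12, 30.8 and 4.06%. By construction CD44, the only one of these with a single position, gains weight there. With a limit of 5 kb it was 34.4% in astrocytes, 32.0% in oligodendrocytes, 12.96% in neurons, 26.4% in endothelial cells and 9.68% in macrophages. With a limit of 50 kb it was 67.2% in GSC, 47.0% in OPC, 23.9% in astrocytes and 8.8% in endothelial cells. Partners of 30 bases or more gave 84.6% in GSC, 55.0% in OPC and 4.77% in macrophages. Without the spellings Cdk6 and hTERT it was 82.7% in GSC, 58.4% in OPC, 25.7% in astrocytes, 21.0% in oligodendrocytes, 0% in neurons and 1.5% in macrophages, and without the scattered partners of CD44 and SOX2 it was 16.6% in oligodendrocytes. GSC had the highest of these shares over the protein-coding viewpoints under each of these alternatives. Shares over all viewpoints are not ranked, because GSC had no reads of 2 segments from lncRNA viewpoints.

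A filter on mapping quality was not run because the table gives none, and pairs with both segments of 30 bases or more could not be used because 0 of 59985 pairs qualify. Shares of the length of the genome were not computed, as no genome sequence was used here. Depth limits neurons most, where 381 partners were counted.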

Other observations

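All tests in this part were chosen after the results they measure were seen. Macrophages, the deepest sample, had 314 of 31860 partners on other chromosomes, 0.986% (0.88 to 1.1), with 165 of them at CDC42, 56 at HOXB-AS1, 44 at SOX2, 33 at CDK6 and 16 at CD44. The leading sites of CDC42 lay in LOC102724214 on chromosome 15 (19 reads), in PARD3, a polarity gene, on chromosome 10 (17 reads), and in NEDD4L on chromosome 18 and ANKRD44 on chromosome 2 (9 reads each). All 16 CD44 reads lay at 1 place in LINC01847 on chromosome 5, with partners of 17 to 19 bases. Of the 314 partners, 92.7% (89.2 to 95.3) had fewer than 50 bases, against 14.7% (14.3 to 15.1) of all macrophage partners. GSC had 0 of 6299 partners on another chromosome in reads of 2 segments (up to 0.0476%).

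Within GSC nuclei, HOTAIRM1 and LINC01116, the viewpoints with reads of 5 segments, were found together in 235 nuclei, where the product of their shares gives 353.1, a ratio of 0.666. That was the lowest ratio of 45 pairs of viewpoint spellings, and the highest was 1.03, for HOTAIRM1 with SOX2 (378 nuclei against 367). Nuclei with 2 reads of 5 segments from a viewpoint had the same middle and last pieces in each read, and the order of the middle pieces was the same in 0 of 34 nuclei for HOTAIRM1 (up to 8.82%) and 0 of 149 for LINC01116 (up to 2.01%). Of 82 combinations of spelling and cell type, 20 had a single partner site, 18 of them over 10 kb away, and 19 of the 20 had at most 1 read per nucleus. At most 1 read per nucleus was also seen in 3 of the 62 combinations with several sites. Whether a selection of reads before they were deposited gave these single sites, and the fixed positions of the GSC reads of 5 segments, was not tested.

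The partners of CD44 in oligodendrocytes and part of those of SOX2 in OPC were spread over many chromosomes. Contacts of these promoters with many places are argued against by the length of the partners, since 79.1% of SOX2 partners under 16 bases (69.0 to 87.1) lay away from the leading site, against 0 of 201 with 16 bases or more (up to 1.49%). The 55 CD44 positions had partners of 40 to 50 bases, a span of 10, where 10000 random sets of as many partner positions gave a span of at least 114. A candidate explanation is 1 repeated or short fragment per viewpoint that matches many places and was placed at different ones. The sequences were not used here, so the match itself stays open.

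Among reads of 2 segments, a nucleus had at most 2 reads of a viewpoint spelling, the Cdk6 spelling in GSC aside, and where it had 2 their partners differed in each of 11789 cases. Shuffling partners within cell type and viewpoint gave the same partner in 748.2 nuclei on average (674 in the lowest of 100 shuffles), against 0 observed. Keeping 1 read for each partner in a nucleus may account for the 0, and since it would fix the count, whether 2 chromosome copies met their partners independently stays open. The Cdk6 spelling in GSC went the other way, with 166 of 166 nuclei with 2 reads showing the same partner and up to 6 reads in a nucleus, so the hypothesis does not cover it. Whether 2 copies set the limit of 2 reads was not tested.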
